A study of Homo sapiens with 8 samples.

How the data were processed

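Gene expression was measured in TC71 cells, an established human Ewing sarcoma line, on 8 Affymetrix arrays. Per the labels' protocols, biotin-labelled cRNA was prepared from 6 µg of total RNA for each array. The labels place 2 arrays in each of 4 groups: cells infected with a scramble control shRNA, cells infected with an SYK shRNA, cells exposed to the SYK inhibitor GS-9973 at 2 µmol/L for 24 h, and DMSO control cells. The sample titles spell the inhibitor GS-9972, whereas the condition label and the design text spell it GS-9973 or GS9973, and the latter name is used here.

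The values deposited by the authors are log2 expression values, 1 per probe set and array. Their scale was taken from the values, which ran from 2.06 to 14.81 with array medians between 6.01 and 6.05. At equal rank, the sorted arrays differed by at most 0.168, so the arrays had been brought to nearly 1 distribution before deposit. Per the submitters' processing notes, the R package affy was used. Its version and the methods of background correction, normalization and probe summary are not given in the sources used here. A method that gives all arrays nearly the same distribution removes any change shared by most genes. Each fold change is therefore relative to the bulk of the transcripts on the array, and dim probe sets may understate a change. No count or depth exists for such data, and the number of arrays limits the precision.

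The table held 54675 probe sets. Of these, 62 were control probe sets, 41091 were named with 1 gene in the platform annotation, 1801 with several genes and 11721 with none. Control probe sets and those with several genes or none were left out of the tests. An identifier in the human RefSeq gene table was found for 41037 of the probe sets with 1 gene, or 99.87%. The probe set with the highest mean over all 8 arrays stood for each gene, which gave 19775 genes, and no filter on dim genes was applied. Neither the labels nor the table name a genome build, so no coordinates are given.

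A linear model with 4 group means and 4 residual degrees of freedom was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes). The empirical Bayes step added 3.46 prior degrees of freedom, for a total of 7.46. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes were called changed. The comparisons were SYK shRNA against scramble shRNA, GS-9973 against DMSO, scramble shRNA against DMSO, and the difference between the first and the second of these. Errors of log2 fold changes are the moderated standard errors of limma (SE), and intervals are 95% intervals from the same fit. The overlap of called genes was set against the number that independent lists would share. The Fisher's exact test fixed for it is not reported, because the comparisons share 1 residual variance and the lists are not independent.

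Before the data were examined, 24 gene lists were written from general knowledge, and the groups, tests, most of the other settings and the rule for named genes were fixed. The lists hold MYC targets, genes activated and genes repressed by EWS-FLI1, SYK and antigen-receptor signalling, S phase, G2 and M phase, apoptosis regulators, p53 targets, interferon response, integrated stress and unfolded protein response, cholesterol biosynthesis and uptake, aryl hydrocarbon receptor and xenobiotic response, MAPK output and immediate-early genes, NF-kB targets, hypoxia and glycolysis, extracellular matrix and adhesion, neuronal genes, long noncoding RNAs, splicing factors, ribosomal proteins, histones, and markers of epithelial, blood and fibroblast cells. Each list was tested against the other genes with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and the rotation test fry were alternatives.

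Named genes followed a fixed rule. SYK, MYC and MALAT1 were always reported. In the comparisons of SYK shRNA and of GS-9973, the rule took the 10 called genes with the largest log2 fold change in each direction, provided that the values of the groups did not overlap. In the other comparisons it took 5 per direction, and among shared genes up to 5 per direction. From each list it took up to 4 called members with the largest change, or the member with the largest change, as a value, where none was called. Genes named outside this rule are said to have been chosen after their values were seen.

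The fitting procedure was tested on simulated data built on the 19775 genes. For SYK shRNA against scramble shRNA, 44.8%, 95.5% and 98.5% of genes changed by 0.5, 1 and 2 log2 units were recovered, with 4 false calls. For GS-9973 against DMSO the shares were 44.8%, 85.1% and 97%, also with 4 false calls. The simulated noise was normal and independent between genes, with a variance per gene drawn from the fitted prior and equal in all groups. These are the assumptions of limma, so the shares do not measure how it performs on the real arrays. There, the difference between replicates had an SD over genes of 0.201 for scramble shRNA and 0.13 for DMSO.

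RNA quality was followed with the 3' and 5' control probe sets of ACTB and GAPDH and with the 18S rRNA probe sets. A probe set of the bioB spike control was also read. Other settings tried were quantile normalization, median centring, leaving out the dimmest 25% or 50% of genes, the mean of all probe sets of a gene, eBayes with trend and robust estimation, only the arrays of 1 comparison, the replicate number as a block, each array left out in turn, and stricter thresholds. SYK shRNA against DMSO, and the tests without probe sets whose names end in _x_at or _s_at, which may detect several transcripts, were added after the data had been seen. So were 100 simulations with no change in any group, drawn from the moderated variances, for comparisons that share arrays. With 2 arrays per group, neither outlier tests within groups nor counts of other splits of the arrays were run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.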

Results

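Transcript levels were measured on 8 arrays of TC71 cells, a human line derived from Ewing sarcoma, a tumour of bone and soft tissue that in most cases carries an EWSR1-FLI1 gene fusion. SYK, a non-receptor tyrosine kinase best known from antigen-receptor signalling, was targeted by a stable shRNA or by GS-9973 (entospletinib), a small-molecule SYK inhibitor, applied at 2 µmol/L for 24 h. Each was set against its own control, scramble shRNA or DMSO, with 2 arrays in each of the 4 groups. The correlation between the replicate arrays of a group was taken over all deposited probe sets. It was 0.9963 for scramble shRNA, 0.9976 for SYK shRNA, 0.9978 for GS-9973 and 0.9982 for DMSO. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical. The 5' probe set of 18S rRNA read 11.21 ± 0.72 (SD, n = 2) for scramble shRNA, 11.64 ± 0.23 for SYK shRNA, 12.46 ± 0.04 for GS-9973 and 12.65 ± 0.03 for DMSO. The log2 difference between the 3' and 5' ACTB probe sets was 1.81 on the second GS-9973 array and between 1.06 and 1.37 on the other 7 arrays. For GAPDH this difference was 0.22 on the second GS-9973 array and between 0.25 and 0.33 on the other 7, so the 2 controls disagreed on that array. The bioB spike control read 9.38 and 9.36 on the scramble shRNA arrays and 9.10 and 9.11 on the arrays labelled SYK shRNA. It read 8.98 and 9.04 on the GS-9973 arrays and 8.96 and 8.94 on the DMSO arrays. Scramble shRNA arrays thus differed on an added control from SYK shRNA arrays, and by more from DMSO arrays. A technical difference is therefore possible between the shRNA groups and between either of them and DMSO.

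The target of the shRNA was examined first. The 4 SYK probe sets read between 3.96 and 5.92 on all 8 arrays. Their means lay at the 14.8th to 37.3rd percentile of the 41091 probe sets named with 1 gene. SYK mRNA was not lower on the arrays labelled SYK shRNA: the log2 fold change against scramble shRNA was 0.00 ± 0.14 (SE, n = 2 per group, limma adjusted p = 0.996), with a 95% interval from -0.33 to 0.32. The 4 probe sets gave log2 fold changes between -0.03 and 0.19. The signal lay in the dim range of the arrays, where a fold change may be understated, so the knockdown named in the labels was not detectable at the mRNA level here. Every direction given for these arrays therefore rests on the label alone. Under GS-9973, which targets the protein, the SYK log2 fold change was 0.00 ± 0.14 (adjusted p = 0.993).

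MYC and MALAT1, which the series title names beside SYK, did not pass the threshold in either comparison. MYC, a transcription factor that drives growth genes, was measured near the top of the range, with a mean of 13.03 in scramble shRNA cells. Its log2 fold change was -0.05 ± 0.08 on the arrays labelled SYK shRNA (adjusted p = 0.787) and -0.11 ± 0.08 under GS-9973 (adjusted p = 0.596). The 95% intervals, in folds, ran from 0.845 to 1.1 and from 0.814 to 1.06. Of 53 measured MYC targets, 0 were called in either comparison, and the list as a whole did not pass with camera (adjusted p = 0.404 for SYK shRNA and 0.504 for GS-9973), though it did for SYK shRNA without the dimmest 50% of genes (adjusted p = 0.0337). Adjusted over the list alone, 1 MYC target was higher and 2 were lower for SYK shRNA, and 1 was higher and 1 lower for GS-9973.

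MALAT1, an abundant nuclear long noncoding RNA, had log2 fold changes of -0.83 ± 0.26 on the arrays labelled SYK shRNA (SE, limma adjusted p = 0.182) and -0.60 ± 0.26 under GS-9973 (adjusted p = 0.328), by its brightest probe set. The first of these values was -0.48 without scramble shRNA replicate 1, -0.50 without SYK shRNA replicate 1, -1.19 without scramble shRNA replicate 2 and -1.16 without SYK shRNA replicate 2. All 12 MALAT1 probe sets were lower on the arrays labelled SYK shRNA than on scramble shRNA arrays, by log2 fold changes between -2.01 and -0.17, and 0 of them were called. Under GS-9973, 10 of the 12 were lower, with log2 fold changes between -0.75 and 0.27, and 0 were called. The same 12 probe sets were all higher on scramble shRNA arrays than on DMSO arrays, and 1 of them, singled out after its values were seen, passed (1.01 ± 0.12, adjusted p = 0.0397). Across the 12, the arrays labelled SYK shRNA lay a median of 0.30 log2 units above DMSO (SD 0.59 over probe sets), with 9 probe sets above it. The brightest probe set went the other way, with a mean of 10.56 against 10.81 for DMSO. Without the probe sets that may detect several transcripts, the log2 fold change of MALAT1 was -2.01 for SYK shRNA and 0.02 for GS-9973. As the mean of all its probe sets it was -0.74 and -0.25.

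**Figure D1:**
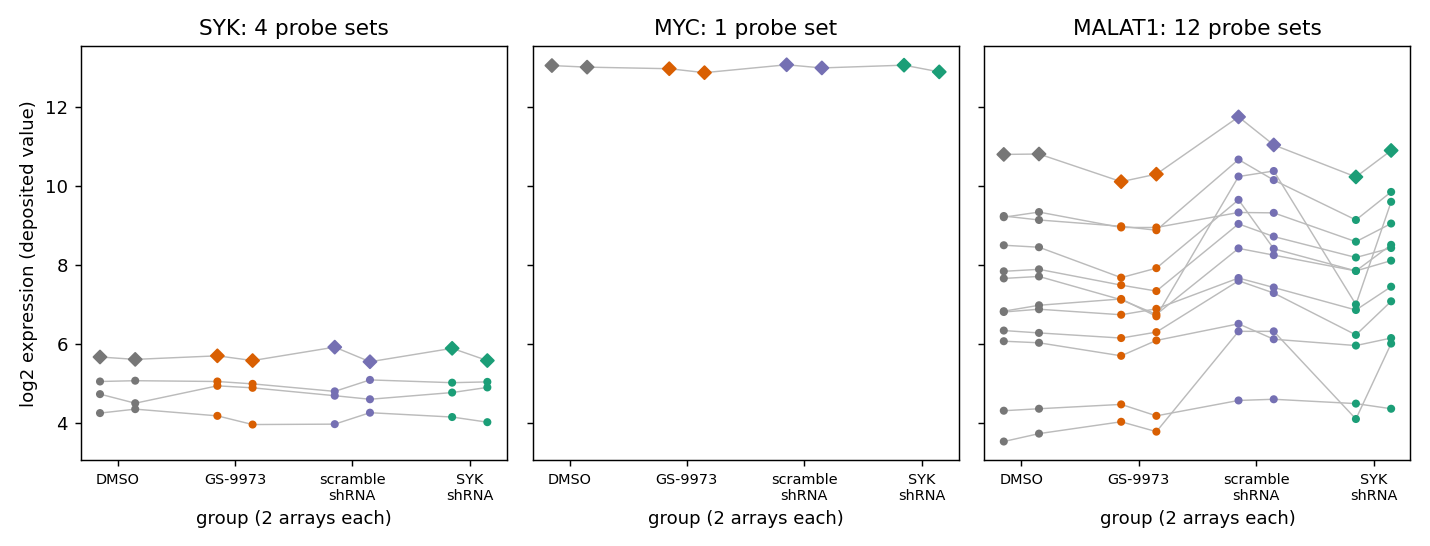
Deposited log2 values (y axis) of every probe set of SYK, MYC and MALAT1 on the 8 arrays, 2 per group (x axis). Diamonds mark the probe set with the highest mean, circles the others, and grey lines join the values of 1 probe set. The 4 SYK probe sets stay between 3.96 and 5.92, while all 12 MALAT1 probe sets have a higher mean on scramble shRNA arrays than on the arrays labelled SYK shRNA.

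The first comparison asked how stable SYK shRNA changed the transcriptome relative to scramble shRNA. MMP1, an interstitial collagenase, fell by 2.12 on the log2 scale (SE 0.15, adjusted p = 0.00266), and RARRES2, the chemoattractant chemerin, fell by 1.93 (SE 0.12, adjusted p = 0.00266). P2RX7, an ATP-gated ion channel, had a log2 fold change of -1.65 ± 0.11, SERPINF1, a secreted serpin also called PEDF, one of -1.53 ± 0.16, and SLC38A4, an amino acid transporter, one of -1.49 ± 0.21. SLC38A4 read in the dim range in both groups, with means of 4.97 for scramble shRNA and 3.48 for SYK shRNA, and its other probe set gave -0.04, so the size of its change is imprecise. Its DMSO mean of 3.67 lay near that of SYK shRNA, so the scramble shRNA arrays were the ones that stood apart. The cancer-testis antigen gene MAGEA12 (-1.86 ± 0.13), the elongation factor gene TCEA3 (-1.80 ± 0.21), the imprinted gene MEST (-1.61 ± 0.11), SUSD5 (-1.41 ± 0.16) and the carboxypeptidase inhibitor gene LXN (-1.39 ± 0.12) completed the 10 largest decreases. MAGEA12 belongs to a family of near-identical genes whose probes can be shared, so its identity is uncertain.

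The largest increases were smaller. PROK2, which encodes a secreted prokineticin, rose 2.13-fold (log2 fold change 1.09 ± 0.10, adjusted p = 0.0076). The zinc finger genes ZNF518B (1.05 ± 0.12) and ZNF595 (0.91 ± 0.08), the sialyltransferase gene ST6GAL2 (0.96 ± 0.11), and CLEC7A (0.87 ± 0.10), the receptor dectin-1 that signals through SYK in myeloid cells, also rose. The other named increases were WDFY3-AS2 (0.80 ± 0.11), MAB21L3 (0.79 ± 0.07), SLC16A4 (0.78 ± 0.12), SPATA17 (0.75 ± 0.11) and the noncoding MOCS2-DT (0.75 ± 0.11). FAS, a death receptor on both the apoptosis and the p53 lists, had a log2 fold change of 0.69 ± 0.09 (adjusted p = 0.0292), which was 0.00 without the probe sets that may detect several transcripts.

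In all, 139 of 19775 genes passed, 44 higher and 95 lower on the arrays labelled SYK shRNA, and 83 of them changed at least 1.5-fold. Higher calls made up 31.7%, against 45.5% (65 higher and 78 lower) after median centring of the arrays. The balance turned without the dimmest 50% of genes, with 302 higher and 252 lower, and with trend and robust estimation, with 328 higher and 288 lower. Replicate values did not overlap between the groups for any of the 139, against 42.9% of all genes and 33.3% by chance. Selection by p-value favours such genes, so this is no separate support for the calls. With limma, leaving out 1 array moved the count to 35 (scramble shRNA replicate 1), 29 and 15 (SYK shRNA replicates 1 and 2), 41 (either GS-9973 array) or 37 (either DMSO array), and to 169 without scramble shRNA replicate 2. Of 37 named results, 21 rested on genes with several probe sets, which all moved 1 way for 13. At least 1 probe set went the other way for SYK, ZNF518B, CLEC7A, TCEA3, COL3A1, CALD1, COL6A1 and FAS. Another probe set moved the same way by a much smaller log2 fold change for ST6GAL2 (0.14), ZNF595 (0.11), P2RX7 (-0.30), S100A6 (-0.29) and SLC38A4 (-0.04). Of 34 named genes that were called, 12 had a group mean under 5.92, the highest SYK reading, where sizes are imprecise: SLC38A4, ST6GAL2, PROK2, LXN, SPATA17, TCEA3, MAB21L3, SUSD5, MAGEA12, MEST, P2RX7 and DCX.

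**Figure D2:**
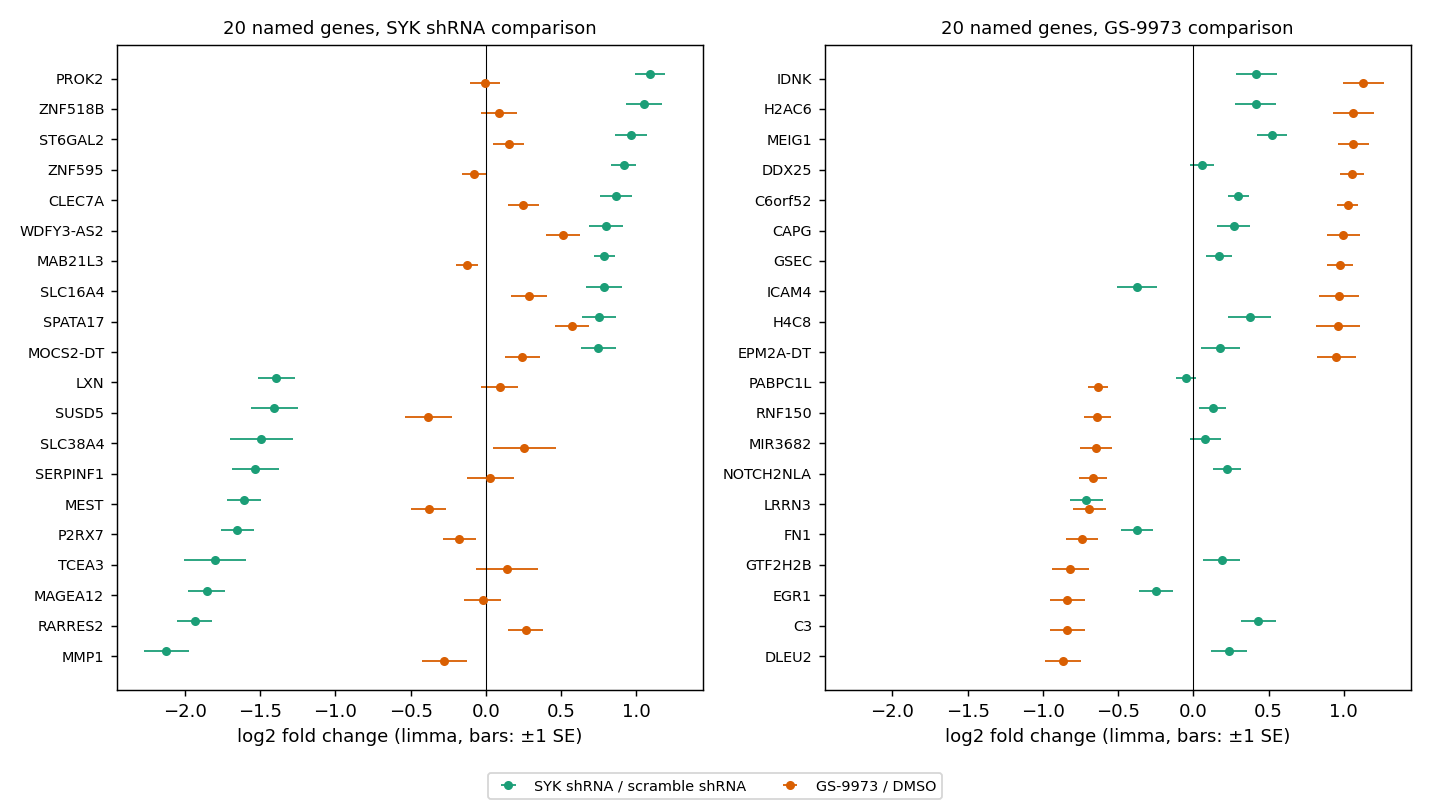
Log2 fold changes (x axis) of the 10 largest increases and the 10 largest decreases of the SYK shRNA comparison (left) and of the GS-9973 comparison (right), with both comparisons drawn for each gene. Points are limma estimates from 2 arrays per group and bars are 1 SE. MMP1 has -2.12 for SYK shRNA, and IDNK has 1.13 for GS-9973.

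Among the gene lists, the interferon response stood out on the arrays labelled SYK shRNA. Of 40 measured members, 37 had positive and 3 negative log2 fold changes, with a median of 0.49 (camera adjusted p = 1.83e-16; adjusted p = 0.594 with an estimated correlation). Over all genes limma called 0 members, and 26 were higher when adjusted over the list alone. MX1, an antiviral GTPase gene, had the largest value (1.02 ± 0.35, adjusted p = 0.212). The list mean was 8.66 and 9.09 on the scramble shRNA arrays and 9.38 and 9.26 on the arrays labelled SYK shRNA. The scramble shRNA array with the lower mean, replicate 1, also had the lowest 18S value, 10.7, and without it the median was 0.294 and the difference in list means 0.23 (SE 0.119), against 0.443 (SE 0.172) with all arrays.

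The histone list was also higher, with 10 of 11 members positive and a median of 0.31 (adjusted p = 0.00117; adjusted p = 0.594 with an estimated correlation). Of these, 0 were called over all genes and 5 adjusted over the list alone, and H2BC4 had 0.78 ± 0.16 (adjusted p = 0.0754). Against DMSO the histone list mean of the arrays labelled SYK shRNA was -0.071 (SE 0.106), and that of scramble shRNA -0.352. The histone median was 0.201 without scramble shRNA replicate 1 and 0.191 without SYK shRNA replicate 2. Genes that EWS-FLI1 is known to repress were lower as a list: 21 of 27 were negative, with a median of -0.11 (adjusted p = 0.0028; adjusted p = 0.594 with an estimated correlation). S100A6 (-0.94 ± 0.10), CALD1 (-0.90 ± 0.14) and COL6A1 (-0.89 ± 0.13) fell, and 6 members were lower when adjusted over the list alone. Against DMSO this list mean was 0.011 (SE 0.04) on the arrays labelled SYK shRNA and 0.188 on scramble shRNA arrays. Both calls were lost without SYK shRNA replicate 2 (adjusted p = 0.0509 for each). Over the other settings the adjusted p reached down to 1.99e-05 for histones and 0.000124 for the repressed genes.

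Fibroblast markers were lower, with 10 of 14 negative and a median of -0.14 (adjusted p = 0.0263; adjusted p = 0.594 with an estimated correlation). COL3A1, a fibrillar collagen gene (-0.97 ± 0.10), and PDGFRB, a growth factor receptor gene (-0.41 ± 0.06), fell. The PDGFRB mean of 7.59 on the arrays labelled SYK shRNA lay near the 7.66 of DMSO, against 8 for scramble shRNA. Adjusted over the list alone, 4 members were lower and 1 was higher. Against DMSO the list mean was -0.034 (SE 0.045) on the arrays labelled SYK shRNA and 0.184 on scramble shRNA arrays. Of the 14 markers, 10 lay above the median gene of these arrays and 4 stood on another list, so that they are not specific to fibroblasts here. The call was lost without scramble shRNA replicate 1 (adjusted p = 0.142), without SYK shRNA replicate 2 (adjusted p = 0.0684), without the dimmest 25% or 50% of genes (adjusted p = 0.115 and 0.102), and without the probe sets that may detect several transcripts (adjusted p = 0.583), the range over settings being 0.00657 to 0.583.

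The other 20 lists had camera adjusted p-values between 0.114 and 0.993 for SYK shRNA. Single members still passed: the chemokine gene CXCL3 on the NF-kB list (0.41 ± 0.06; list adjusted p = 0.114), COL5A1 on the extracellular matrix list (-0.67 ± 0.10; list adjusted p = 0.547), the neuronal gene DCX (-0.78 ± 0.12; list adjusted p = 0.409) and the epithelial gene CLDN7 (-0.78 ± 0.10; list adjusted p = 0.387). The CXCL3 mean of 8.26 on the arrays labelled SYK shRNA lay near the 8.14 of DMSO, against 7.85 for scramble shRNA. Of 15 epithelial markers 3, and of 13 blood cell markers 3, lay above the median gene, and 0 of either stood on another list. The list adjusted p was 0.114 for S phase, 0.993 for G2 and M phase, 0.409 for EWS-FLI1-activated genes, 0.404 for SYK and antigen-receptor signalling, 0.387 for apoptosis regulators and 0.907 for p53 targets. It was 0.404 for MAPK output, 0.175 for cholesterol biosynthesis, 0.938 for the stress response and for hypoxia and glycolysis, and 0.993 for the xenobiotic response and for blood cell markers. Long noncoding RNAs had 0.985, splicing factors 0.404 and ribosomal proteins 0.574. Leaving out 1 array brought some of these lists under the threshold at the preset correlation: without scramble shRNA replicate 1 cholesterol biosynthesis (adjusted p = 0.0324, higher) and epithelial markers (0.0324, lower), and without SYK shRNA replicate 1 S phase (0.0139, higher), NF-kB targets (0.0155, higher) and hypoxia and glycolysis (0.0111, lower). Without SYK shRNA replicate 2 these were cholesterol biosynthesis (0.0382), the stress response (0.0428) and hypoxia and glycolysis (0.000698), all higher, the last in the opposite direction. Signs differed within a list for long noncoding RNAs, whose median was 0.02 and mean -0.04. Camera placed G2 and M phase, the stress response and blood cell markers above the other genes although their medians and means were negative.

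The second comparison asked how 24 h of GS-9973 changed the transcriptome relative to DMSO. Increases predominated. IDNK, a gluconokinase gene, rose 2.19-fold (log2 fold change 1.13 ± 0.14, adjusted p = 0.0291). The histone genes H2AC6 (1.06 ± 0.14) and H4C8 (0.96 ± 0.14) rose, as did MEIG1 (1.06 ± 0.10) and DDX25 (1.05 ± 0.08), which are known from male germ cells. CAPG, an actin-capping protein gene (1.00 ± 0.11), ICAM4, an adhesion molecule gene (0.97 ± 0.13), C6orf52 (1.03 ± 0.07) and the noncoding transcripts GSEC (0.97 ± 0.09) and EPM2A-DT (0.95 ± 0.13) completed the 10 largest increases.

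Among the decreases, DLEU2, a long noncoding RNA that hosts microRNAs, had a log2 fold change of -0.87 ± 0.12 (adjusted p = 0.0349). The complement gene C3 (-0.84 ± 0.12), the immediate-early transcription factor gene EGR1 (-0.84 ± 0.11) and the fibronectin gene FN1 (-0.74 ± 0.11) also fell. The others were LRRN3 (-0.69 ± 0.11), RNF150 (-0.64 ± 0.09), PABPC1L (-0.63 ± 0.06), a probe set assigned to MIR3682 (-0.65 ± 0.10), and GTF2H2B (-0.82 ± 0.12) and NOTCH2NLA (-0.67 ± 0.09), both of which have near-identical copies in the genome and are uncertain.

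In all, 149 genes passed, 121 higher and 28 lower under GS-9973, and 76 changed at least 1.5-fold. Replicate values did not overlap for any of the 149, against 52% of all genes and 33.3% by chance, which again follows largely from the selection. The limma count fell to 0 when either GS-9973 array, either DMSO array or either array labelled SYK shRNA was left out, with 2229 and 2158, 1866 and 1872, and 3104 genes at an unadjusted p under 0.05 in turn, and rose to 221 without either scramble shRNA array. With all 8 arrays, 3108 genes had an unadjusted p under 0.05. Of 34 named results, 20 rested on genes with several probe sets, which disagreed in sign for SYK, MALAT1, DLEU2, EGR1, FN1, COL3A1 and ACTA2. Another probe set gave 0.01 for IDNK and -0.11 for PABPC1L. EPM2A-DT, EGR1 and MIR3682 had a group mean under 5.92, in the dim range.

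**Figure D3:**
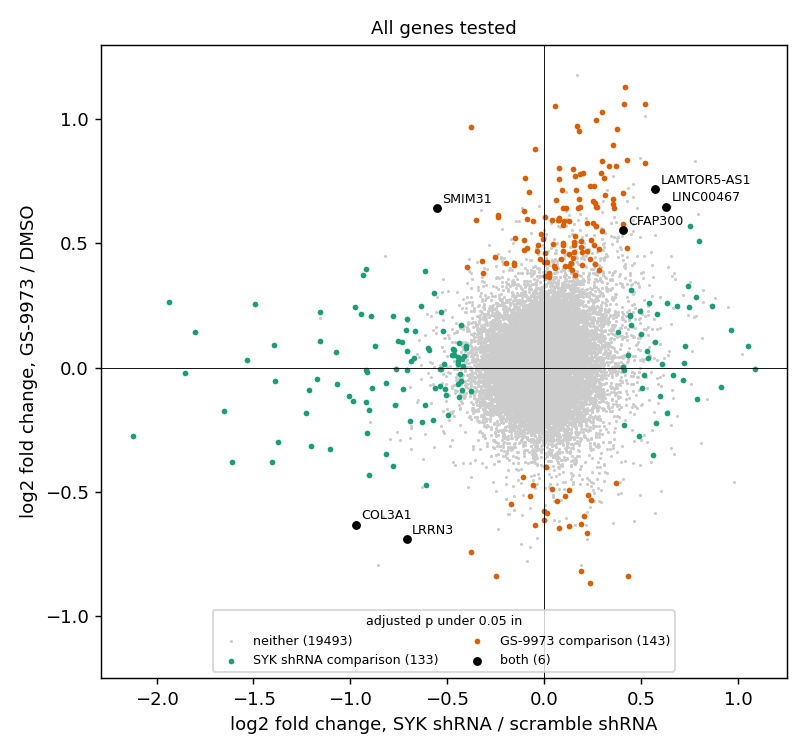
Log2 fold change of each of the 19775 genes for SYK shRNA against scramble shRNA (x axis) and for GS-9973 against DMSO (y axis), with 1 point per gene. Colours mark genes with an adjusted p under 0.05 in 1 comparison (133 and 143 genes) or in both (6 genes, named).

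Histones showed the largest shift of any list under GS-9973. Of 11 measured members, 9 were positive, with a median of 0.59 (camera adjusted p = 6.91e-07; adjusted p = 0.421 with an estimated correlation). Over all genes 5 were called higher, H2AC6, H4C8, H2BC5 (0.81 ± 0.11), H2BC9 (0.76 ± 0.10) and H2BC21, which was chosen after its values were seen (0.59 ± 0.08), and 9 were higher and 1 lower adjusted over the list alone. Most histone messages of dividing cells lack a poly(A) tail, and several histone genes have near-identical copies. The list mean was 10.50 and 10.62 on the GS-9973 arrays and 9.96 and 10.03 on the DMSO arrays. The second GS-9973 array was the one with the ACTB 3' to 5' difference of 1.81, whereas its GAPDH difference, 0.22, was the lowest of all arrays.

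Genes of G2 and M phase were lower under GS-9973: 43 of 52 were negative, with a median of -0.10 (adjusted p = 7.9e-08; adjusted p = 0.421 with an estimated correlation). MKI67, a proliferation marker (-0.61 ± 0.10), and SMC4, a condensin subunit gene (-0.52 ± 0.06), fell, and 9 members were lower adjusted over the list alone. Splicing factors were lower with 25 of 32 negative and a median of -0.09 (adjusted p = 0.000125; adjusted p = 0.421 with an estimated correlation). Of them, limma called 0 over all genes or adjusted over the list alone, and SRRM2 had -0.36 ± 0.08 (adjusted p = 0.0801).

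MAPK output and immediate-early genes were lower, with 17 of 24 negative and a median of -0.14 (adjusted p = 0.000776; adjusted p = 0.317 with an estimated correlation). EGR1 was the member called over all genes, and 6 were lower adjusted over the list alone. Of 20 long noncoding RNAs, 14 were negative, with a median of -0.12 (adjusted p = 0.00763; adjusted p = 0.458 with an estimated correlation). DLEU2 was the called member, and 3 were lower adjusted over the list alone. Genes that EWS-FLI1 represses were lower with 17 of 27 negative and a median of -0.05 (adjusted p = 0.0149; adjusted p = 0.458 with an estimated correlation). FN1 was the called member, and 4 were lower adjusted over the list alone. Its median was -0.018 without GS-9973 replicate 2. This last call was lost without DMSO replicate 2 (adjusted p = 0.0648) and without the probe sets that may detect several transcripts (adjusted p = 0.826), with a range of 0.000516 to 0.826 over settings.

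The other 18 lists had camera adjusted p-values between 0.124 and 0.936 for GS-9973. Called members of these were TM7SF2, a sterol reductase gene (0.49 ± 0.07; cholesterol list adjusted p = 0.836), the quinone reductase gene NQO1 (0.42 ± 0.06; xenobiotic list adjusted p = 0.596), and ACTA2 (0.81 ± 0.10) and COL3A1 (-0.63 ± 0.10), which moved in opposite directions on the fibroblast list (adjusted p = 0.743). The list adjusted p was 0.936 for the interferon response, where 23 of 40 members were positive, 0.124 for S phase, 0.161 for the extracellular matrix list, where FN1 and COL3A1 fell, 0.936 for SYK and antigen-receptor signalling and 0.689 for EWS-FLI1-activated genes. It was 0.504 for apoptosis regulators, for NF-kB targets, for hypoxia and glycolysis and for the stress response, 0.596 for p53 targets, 0.348 for neuronal genes, 0.867 for ribosomal proteins, 0.723 for epithelial and 0.877 for blood cell markers. At other settings S phase passed with quantile normalization (adjusted p = 0.0293), the extracellular matrix without the dimmest 25% or 50% of genes (adjusted p = 0.0477 and 0.0282) and neuronal genes with the mean of all probe sets (adjusted p = 0.0254). The median and the mean had opposite signs for neuronal genes (0.01 and -0.06), NF-kB targets (0.02 and -0.03), cholesterol biosynthesis (-0.02 and 0.02) and fibroblast markers (-0.02 and 0.05), and, both within 0.01 of 0, for EWS-FLI1-activated genes and blood cell markers.

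**Figure D4:**
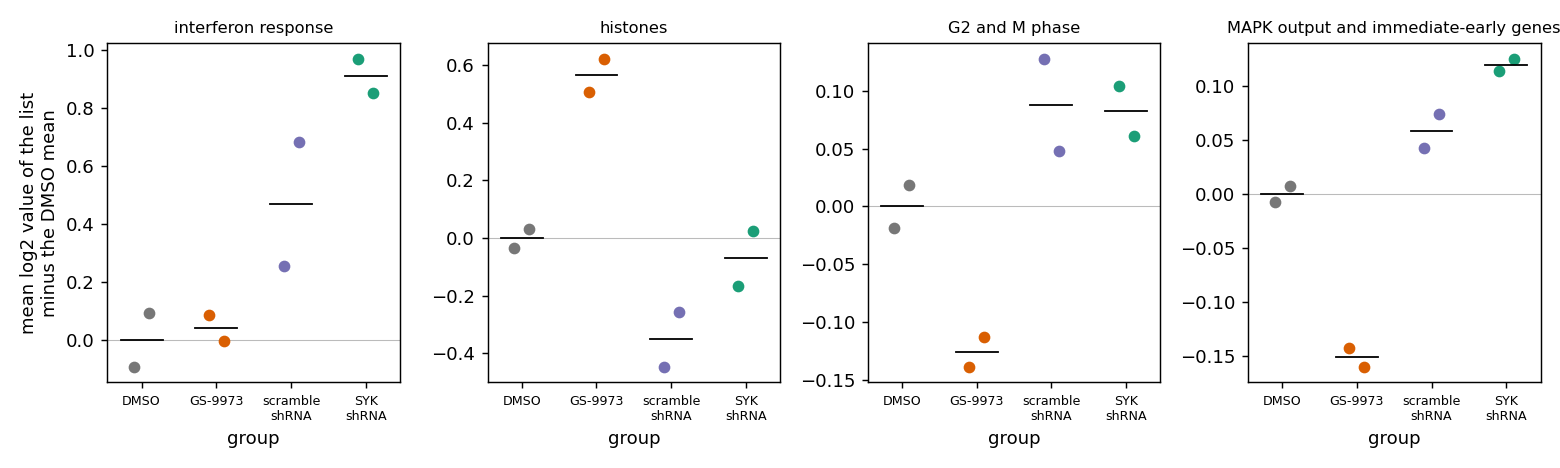
Mean log2 value of the members of 4 gene lists on each array, minus the mean of the DMSO arrays (y axis, with a separate scale per panel), by group (x axis). Points are arrays and black bars are means of 2 arrays. For the interferon list the scramble shRNA mean is 0.47 and the mean of the arrays labelled SYK shRNA 0.91 above DMSO, and for histones GS-9973 is 0.57 above DMSO.

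The design sets the arrays labelled SYK shRNA and the SYK inhibitor side by side, although no decrease of SYK mRNA was detected on the former. The comparisons share no array, but each was tested with the residual variance pooled over all 8. LINC00467 (0.63 ± 0.07 for SYK shRNA and 0.65 ± 0.07 for GS-9973), LAMTOR5-AS1 (0.57 ± 0.07 and 0.72 ± 0.07) and CFAP300, a gene of motile cilia (0.41 ± 0.06 and 0.55 ± 0.06), rose in both. LRRN3 (-0.71 ± 0.11 and -0.69 ± 0.11) and COL3A1 (-0.97 ± 0.10 and -0.63 ± 0.10) fell in both. COL3A1 was itself higher in scramble shRNA than in DMSO cells (0.81 ± 0.10, adjusted p = 0.033, with 0.08 to 0.96 over its probe sets), and its mean of 9.57 on the arrays labelled SYK shRNA lay near the 9.73 of DMSO. Independent lists would share 0.269 higher and 0.135 lower genes. A gene of low pooled variance can be favoured in both comparisons, so these may not be the numbers expected with no shared change, and no p-value is given for the overlap. With genes placed in 20 groups by that variance, a step added after the data were seen, 0.33 and 0.145 would be shared. With only the arrays of each comparison, limma called 11 and 0 genes and 0 were shared. SMIM31, chosen after its values were seen, was called in opposite directions, at -0.55 ± 0.07 for SYK shRNA and 0.64 ± 0.07 for GS-9973, and was 1.23 higher in scramble shRNA than in DMSO cells (adjusted p = 0.00547). For COL3A1, the GS-9973 log2 fold change was 0.24 without the probe sets that may detect several transcripts, and 1 shared gene was then counted in place of 5. The count of shared genes was 2 without scramble shRNA replicate 1, 14 without scramble shRNA replicate 2, and 0 with limma without any of the other 6 arrays.

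Across all genes the log2 fold changes of the comparisons correlated weakly (Pearson r = 0.136, Spearman rho = 0.118), and 53.8% of genes had the same sign. Pearson r was 0.067 without scramble shRNA replicate 1, 0.044 without GS-9973 replicate 2, 0.058 without DMSO replicate 1 and as high as 0.201 without GS-9973 replicate 1. Genes are not independent replicates, so no p-value is given. Of the 139 genes called for SYK shRNA, 79 (56.8%) had the same sign under GS-9973, and of the 149 called for GS-9973, 104 (69.8%) had the same sign for SYK shRNA.

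The change differed between the comparisons for 26 genes by the test of the difference itself, 5 with a higher and 21 with a lower change for SYK shRNA. RARRES2 differed by -2.20 ± 0.16 log2 units (adjusted p = 0.0118), MMP1 by -1.85 ± 0.21, MAGEA12 by -1.83 ± 0.18, LXN by -1.48 ± 0.17 and P2RX7 by -1.48 ± 0.16. ZNF595 differed by 0.99 ± 0.12, MAB21L3 by 0.91 ± 0.10, NBEAL1 by 0.84 ± 0.09, ZNF704 by 0.82 ± 0.10 and the neuropeptide gene NTS by 0.76 ± 0.08. Another probe set gave a smaller difference of the same sign for ZNF595 (0.35), NBEAL1 (0.21), ZNF704 (0.36) and P2RX7 (-0.30). The count fell to 5 without scramble shRNA replicate 2, to 9 without SYK shRNA replicate 1 and to 0 with limma without any other array, with at least 1721 genes at an unadjusted p under 0.05. With all arrays 2787 genes had an unadjusted p under 0.05.

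The control groups were compared to measure how far cells infected with scramble shRNA and DMSO control cells differed from each other. TMEM255A (1.73 ± 0.20), TNFRSF9, a receptor of the TNF receptor family (1.65 ± 0.16), LOXL1-AS1 (1.39 ± 0.10, from a dim DMSO mean of 3.62), the neuronal gene GAP43 (1.29 ± 0.13) and QPRT, an enzyme of NAD synthesis (1.24 ± 0.12), were higher in scramble shRNA cells. The gelatinase gene MMP2 (-0.94 ± 0.10), the cytochrome gene CYP1B1 (-0.92 ± 0.13), SCIN (-0.90 ± 0.12), GABRQ (-0.82 ± 0.12) and LPCAT2 (-0.81 ± 0.08) were lower. The DMSO means of TMEM255A (5.0) and TNFRSF9 (5.91) were also dim. Another probe set gave 0.21 for TNFRSF9, -0.07 for SCIN and -0.17 for GABRQ, and 1 went the other way for GAP43, MMP2, CYP1B1 and LPCAT2. In all, 58 genes were higher and 29 lower, or 87 in sum. The limma count lay at 3 and 11 without scramble shRNA replicates 1 and 2, at 53 without either array labelled SYK shRNA, at 3 without either GS-9973 array, and at 2 and 1 without DMSO replicates 1 and 2.

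Between the controls, 8 lists passed at the preset correlation and none with an estimated one, at adjusted p-values between 0.391 and 0.44 for these 8. The interferon response was higher in scramble shRNA cells (38 of 40 positive, median 0.42, adjusted p = 1.19e-15; adjusted p = 0.407 with an estimated correlation; 23 members higher adjusted over the list alone), as was hypoxia and glycolysis (29 of 31 positive, median 0.23, adjusted p = 3.75e-12), where the glycolytic gene PKM rose (0.66 ± 0.10). Histones were lower (10 of 11 negative, median -0.41, adjusted p = 7.75e-06), and so was cholesterol biosynthesis (16 of 21 negative, median -0.14, adjusted p = 0.000201), where IDI1 had -0.46 ± 0.06. EWS-FLI1-repressed genes (adjusted p = 2.12e-05), with TNC (0.95 ± 0.13, and 0.08 by another probe set) and IER3 (0.45 ± 0.07), G2 and M phase (adjusted p = 0.000285), with NCAPD2 (0.54 ± 0.08), fibroblast markers (adjusted p = 0.00162) and the extracellular matrix (adjusted p = 0.02), with COL5A2 (0.55 ± 0.07), were higher. The 18S value was 11.21 in scramble shRNA and 12.65 in DMSO cells. The bioB spike control also differed, at 9.38 and 9.36 against 8.96 and 8.94, so a technical difference between the controls is possible. The other 16 lists had adjusted p-values between 0.0888 and 0.911, and neuronal genes had a median of -0.02 and a mean of 0.18. Of these, long noncoding RNAs passed without scramble shRNA replicate 1 (adjusted p = 0.0268), the stress response without scramble shRNA replicate 2 (0.0286) or either array labelled SYK shRNA (0.0418), and MAPK output without the dimmest 50% of genes (0.0466) or with the mean of all probe sets (0.0312). The interferon median was 0.229 without scramble shRNA replicate 2, the histone median -0.266 without scramble shRNA replicate 1, and the median of EWS-FLI1-repressed genes 0.095 without DMSO replicate 2. Without DMSO replicate 1 it was 0.043 for G2 and M phase and 0.044 for the extracellular matrix, and without scramble shRNA replicate 2 it was 0.117 for G2 and M phase, 0.046 for the extracellular matrix and -0.066 for cholesterol biosynthesis. Calls were lost for G2 and M phase without scramble shRNA replicate 1 (median 0.043, adjusted p = 0.119), and for cholesterol biosynthesis (adjusted p = 0.0597) and the extracellular matrix (adjusted p = 0.107) without scramble shRNA replicate 2. Without the probe sets that may detect several transcripts, the extracellular matrix (adjusted p = 0.15) and fibroblast (adjusted p = 0.845) calls were lost, and IDI1 had 0.17. Over settings, the adjusted p ran from 9.69e-08 to 0.119 for G2 and M phase, from 5.54e-06 to 0.0597 for cholesterol biosynthesis, from 0.00331 to 0.15 for the extracellular matrix and from 0.000495 to 0.845 for fibroblast markers.

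Against DMSO in place of scramble shRNA, an alternative chosen after the data were seen, 592 genes passed on the arrays labelled SYK shRNA, 361 higher and 231 lower. Of the 139 genes called against scramble shRNA, 132 had the same sign and 76 were called in the same direction. Both comparisons use the same SYK shRNA arrays, so agreement is expected with no change at all: in 100 simulations without any change, the 139 genes with the smallest p-values gave a median of 127.5 with the same sign (117 to 133) and 8.5 past the same p-value (2 to 17). For 12 of the 139, scramble shRNA and DMSO cells differed in the opposite direction by the same threshold, against 2 (0 to 7) in the simulations, since the scramble shRNA arrays are shared. By sign alone 114 of the 139 were opposite, fewer than the 128 (119 to 135) of the simulations. The simulations leave out real effects, so neither an excess nor a shortfall is a measure of shared change. Among the 12 were COL3A1, LOXL1-AS1, SMIM31 and ZNF595. ZNF595 had -0.79 in scramble shRNA against DMSO (adjusted p = 0.0237) and 0.12 on the arrays labelled SYK shRNA against DMSO (adjusted p = 0.472).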

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

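The tests of explanations in this part were chosen after the results had been seen, while the tests of the difference between the comparisons were planned. The change for SYK shRNA differed from the change under GS-9973 for 26 genes. Among them were 13 genes named by the fixed rule, given here as the log2 change for SYK shRNA minus that for GS-9973. The difference was -2.20 for RARRES2, -1.85 for MMP1, -1.83 for MAGEA12, -1.48 for LXN, -1.48 for P2RX7, -1.38 for LOXL1-AS1, -1.16 for S100A6 and -1.0 for DDX25. It was 0.76 for NTS, 0.82 for ZNF704, 0.84 for NBEAL1, 0.91 for MAB21L3 and 0.99 for ZNF595.

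With camera at the preset correlation, 8 lists also differed between the comparisons. The change of the interferon response (adjusted p = 4.14e-12), of G2 and M phase (adjusted p = 4.09e-05), of MAPK output and immediate-early genes (adjusted p = 0.000384), of S phase (adjusted p = 0.00631), of NF-kB targets (adjusted p = 0.0129) and of splicing factors (adjusted p = 0.0464) was higher for SYK shRNA. That of fibroblast markers (adjusted p = 0.00396) and of histones (adjusted p = 0.0347) was lower. With an estimated correlation the adjusted p of these lists ran from 0.258 to 0.745, and none passed. At the preset correlation other lists joined them, all higher, when 1 array was left out. These were hypoxia and glycolysis and the stress response without SYK shRNA replicate 2. Long noncoding RNAs joined without scramble shRNA replicate 1 or SYK shRNA replicate 1. Leaving out 1 array at the preset correlation ended the call of S phase (adjusted p = 0.0785) and of NF-kB targets (adjusted p = 0.0828) without SYK shRNA replicate 2. The histone call ended without scramble shRNA replicate 2 (adjusted p = 0.335), SYK shRNA replicate 1 (0.254), GS-9973 replicate 2 (0.186) or DMSO replicate 1 (0.0805). That of splicing factors ended without scramble shRNA replicate 2 (adjusted p = 0.553), SYK shRNA replicate 2 (0.295), GS-9973 replicate 1 or 2 (0.107 and 0.0556) or DMSO replicate 1 or 2 (0.0557 and 0.136).

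The interferon list was higher on the arrays labelled SYK shRNA than on scramble shRNA arrays at the preset correlation (adjusted p = 0.594 with an estimated correlation). A single array as the main source stays open, since the scramble shRNA arrays had list means of 8.66 and 9.09 and the difference in list means without the first of them was 0.230 (SE 0.119), which is under 2 SE. A response to SYK inhibition by either means stays open too, although no decrease of SYK mRNA was detected. The list mean changed by 0.040 (SE 0.172) under GS-9973. It differed between SYK shRNA and GS-9973 by 0.402 (SE 0.244), which is under 2 SE. Camera called this difference at the preset correlation (adjusted p = 4.14e-12) but not with an estimated one (adjusted p = 0.699). A response to shRNA delivery may also contribute, because scramble shRNA cells themselves lay 0.470 above DMSO cells (SE 0.172). Delivery and shRNA sequence change together in this design, so these cannot be told apart.

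Histone transcripts were higher under GS-9973 at the preset correlation (adjusted p = 0.421 with an estimated correlation). Partly degraded RNA on the second GS-9973 array is argued against as the whole source, since the list mean was 0.509 higher (SE 0.139) with the first GS-9973 array alone and 0.623 higher (SE 0.139) with the second alone. Whether RNA on the second array was degraded is itself unclear. Its ACTB 3' to 5' difference of 1.81 was the highest of all arrays, but its GAPDH difference of 0.22 was the lowest. Fewer dividing cells may accompany the shift, as G2 and M phase genes were lower under GS-9973 at the preset correlation (adjusted p = 0.421 with an estimated one), and in scramble shRNA against DMSO cells histones were lower (-0.352, SE 0.106) and G2 and M phase genes higher (0.088, SE 0.036). The other test of this was whether G2 and M phase genes were also lower on the arrays labelled SYK shRNA, where the histone list was higher than in scramble shRNA cells, though its mean against DMSO was -0.071 (SE 0.106). Their mean change there was -0.006 (SE 0.036), which does not decide, and an effect of the inhibitor itself was not tested apart from it. The S phase list mean changed opposite to histones under GS-9973 (-0.044, SE 0.018). It moved with histones for SYK shRNA (0.046, SE 0.018) and for scramble shRNA against DMSO (-0.029, SE 0.018), so the lists of dividing cells do not give 1 answer.

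All 12 MALAT1 probe sets were lower on the arrays labelled SYK shRNA than on scramble shRNA arrays, by a median of 0.68 log2 units. A difference between single cultures or arrays stays open, since the gap between the arrays labelled SYK shRNA had a median of 0.627 over the same probe sets. By the probe set with the largest change, these arrays read 7.0 and 9.6, against 10.24 and 10.38 for scramble shRNA. A loss of MALAT1 below its level in DMSO control cells could not be shown or excluded. Over the 12 probe sets, the arrays labelled SYK shRNA lay a median of 0.301 above DMSO. The SD of 0.59 is a spread over probe sets and does not measure error between arrays. By the brightest probe set, the arrays labelled SYK shRNA lay below DMSO, with means of 10.56 and 10.81. Infection differs between these groups too, and the probe sets share a transcript and are not independent.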

How the results depend on the processing

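The runs against DMSO and without probe sets ending in _x_at or _s_at were chosen after the data were seen; the others were planned. The pseudocount alternative was not run, since the table is in log2. Counts of called genes are given for SYK shRNA (139 in the report), GS-9973 (149), scramble shRNA against DMSO (87), the difference (26) and both in the same direction (5). Without the dimmest 25% of genes they were 442, 528, 358, 130 and 42, and without the dimmest 50% 554, 954, 671, 363 and 84. With trend and robust estimation they were 616, 887, 716, 412 and 68. Quantile normalization gave 211, 207, 84 and 10 for all but GS-9973, which stayed within 1.5 times, and median centring gave 55 for the controls. Using only the arrays of a comparison, with fewer degrees of freedom, gave 11, 0 and 0 with limma, with 0 shared (2273, 4092 and 2466 genes at an unadjusted p under 0.05). Without _x_at and _s_at probe sets the counts were 77, 93, 35, 46 and 1. The mean of all probe sets gave 8 shared genes. An adjusted p under 0.01 left 25, 0, 3, 0 and 0, and at least 1.5-fold 83 and 76, with 3 shared. Against DMSO, 592 genes were called for SYK shRNA.

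With the replicate number as a block, the counts were 64, 14, 23, 0 and 0. The labels do not say that the numbers pair the arrays, and the differences between replicates of 2 groups correlated between -0.231 and 0.175 across genes.

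Leaving out each array in turn, where the lone array of a group is assumed to vary like the other groups, gave 15 to 169 genes for SYK shRNA, 0 to 221 for GS-9973, 1 to 53 for the controls, 0 to 9 for the difference and 0 to 14 shared. No called gene turned its sign. The correlation of log2 fold changes ran from 0.044 to 0.201, and 4 to 7 lists passed for SYK shRNA. The uncalled log2 fold changes near 0 turned sign: SYK ran from -0.19 to 0.18 for SYK shRNA and from -0.06 to 0.05 for GS-9973, and MYC for SYK shRNA from -0.14 to 0.03.

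For SYK shRNA the SYK log2 fold change was 0.03 with quantile normalization, 0.02 with median centring, 0.06 as the mean of probe sets and 0.08 without _x_at and _s_at probe sets. For GS-9973 it was 0.01 with quantile normalization, 0.00 with median centring and 0.01 as the mean of probe sets. Without _x_at and _s_at probe sets, MALAT1 (0.02) and COL3A1 (0.24) under GS-9973, FAS (0.00) for SYK shRNA and IDI1 (0.17) between the controls also turned. With the correlation estimated, camera called 0, 0 and 0 lists for SYK shRNA, GS-9973 and the controls. At the preset value it called 4, 6 and 8. The test fry, which tests a list against no change, called 1, 2 and 5. For SYK shRNA its call was the extracellular matrix (lower, fry adjusted p = 0.00782), and not any of camera's 4 lists. For GS-9973 its calls were MAPK output (0.00648) and the extracellular matrix (0.00672), both lower. It did not call histones (0.0531) or G2 and M phase (0.106). No list called in the report was called in the opposite direction at another setting. Hypoxia and glycolysis, not called there for SYK shRNA, passed in opposite directions without 1 or the other SYK shRNA array. Over all alternatives, called named genes kept direction and call 792 times, lost the call 728 times and turned 3 times, and SYK, MYC and MALAT1, never called in the report, kept their direction without a call 85 times and turned 13 times. Apart from what follows from fewer genes, arrays or degrees of freedom, the cause was not tested. Signal limits the dim genes, SYK among them.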

Other observations

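The tests of gene classes in this part, and the choice of MAGEA6 and DRC9, were made after the results had been seen. In the MAGEA family of cancer-testis antigens, MAGEA6 (-1.07 ± 0.07, adjusted p = 0.00266) fell beside MAGEA12 (-1.86 ± 0.13) on the arrays labelled SYK shRNA, and the other 5 of 7 measured members were not called, with log2 fold changes between -0.23 and 0.02. A shift of the whole family was tested as a hypothesis on these other 5, without the genes that prompted it, and did not pass with camera (adjusted p = 0.763 over 9 tests). Their means of 3.71 to 5.42 in scramble shRNA cells lie in the dim range, where a decrease may go unseen, so the hypothesis stays open. These genes are near-identical copies, so probes shared between family members may report 1 transcript in several places, which the arrays cannot resolve.

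Genes of motile cilia were also looked at, because CFAP300 rose in both comparisons. DRC9, a gene of the axonemal regulatory complex, fell by 1.16 (SE 0.06, adjusted p = 0.00266) on the arrays labelled SYK shRNA, opposite to CFAP300. Under GS-9973, 59 of 113 cilia genes had positive log2 fold changes, with a median of 0.01, and no shift of the class was found (camera adjusted p = 0.792). Antisense and divergent transcripts, such as EPM2A-DT, were examined in the same way. Of 998, 10 were called higher and 0 lower under GS-9973, where 554 were positive, and the class did not pass either (adjusted p = 0.763).

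LOXL1-AS1, named by the fixed rule between the controls, was higher in scramble shRNA cells than in DMSO cells (1.39 ± 0.10, adjusted p = 0.00773) and lower on the arrays labelled SYK shRNA than on scramble shRNA arrays (-1.16 ± 0.10, adjusted p = 0.00572). Group means were 5.01 for scramble shRNA, 3.86 for SYK shRNA, 3.84 for GS-9973 and 3.62 for DMSO. All 4 lie in the dim range of the arrays, so the sizes of these changes are imprecise.

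The first principal component of the gene values held 40.7% of the variance and the second 19.9%. On the first, both groups of infected cells had negative scores and both GS-9973 and DMSO arrays positive ones. On the second, the scramble shRNA arrays scored 10.7 and 12.7 and the arrays labelled SYK shRNA -11 and -11.8. The third held 11.9% and parted the scramble shRNA arrays from each other, at -13.6 and 12.1.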
